A study of Mus musculus with 4 samples.

How the data were processed

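Hippocampal RNA was measured in 4 deposited samples from C57BL/6J mice aged 4 months that carried P2RY12CreER and Rpl22HA. In this RiboTag line the Cre recombinase, active in microglia, switches on a tagged ribosomal protein, so that ribosomes and the messages bound to them can be pulled down with an antibody against the tag. Per the labels' protocols the RNA came from such a ribosome pulldown and was enriched for polyA. Each sample pooled 2 mice, and the samples were described as technical replicates. The sample titles placed 2 samples in the control group, trained and then left to sleep for 6 h, and 2 in the sleep-deprived group, trained and then kept awake for 6 h. The treatment field of the labels names sleep deprivation for all 4 samples, so groups were taken from the titles.

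Each deposited file lists, per the file headers, the length, effective length, TPM and estimated read number of 116546 mouse transcripts. Salmon, DESeq2 and the genome build mm10 are named in the submitters' processing notes. The Salmon version, the read layout and the transcript annotation are not given in the sources used here. In the files, 99.2% of transcripts longer than 1000 bases had an effective length exactly 250 bases below their length. The estimated counts are the authors' own, deposited as fractional values per transcript without normalization. The TPM values, deposited in the same files, are the authors' length-scaled abundances and were used only to weight transcript lengths within a gene. A transcript estimate divides reads shared between similar transcripts by a model, so values of near-identical genes, overlapping genes and antisense partners are uncertain. Strand use by the authors is not given in the sources used here.

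Transcripts were matched by identifier, without version, to GENCODE mouse release 21 on GRCm38, the assembly that mm10 denotes. The match covered 115898 transcripts (99.4%), and their estimated counts were summed to 35427 genes. Reads on the unmatched transcripts were left out, which removed between 0.339% and 0.366% of the estimated reads of a file. The files held 14877011 and 14833320 estimated reads in control and 14473030 and 14431647 in sleep-deprived samples.

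Replicates were compared before they were averaged. Over genes with at least 20 reads, chi-square per degree of freedom was 0.335 between the control files (14695 genes) and 0.226 between the sleep-deprived files (14409 genes), where independent sequencing of one library gives about 1. Between files of different groups it lay between 69.2 and 69.4. The 2 files of a group therefore differed by less than the sampling noise, and their mean was used as 1 library. This left 1 independent library per group and no residual degrees of freedom. The planned edgeR quasi-likelihood test, its robust form, the DESeq2 Wald test, limma voom, the replicate block, camera, fry, camera with an estimated correlation, and the adjusted p thresholds were not run, and no p-value is given.

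In their place a rule of size was used. Estimated counts were rounded to whole numbers and scaled by TMM in edgeR 4.0.16 under R 4.3.3, which gave CPM. The 14907 genes kept by edgeR's filterByExpr with a minimum count of 10 are called measured. A gene was called higher or lower in the sleep-deprived library when the ratio was at least 2-fold and the exact conditional (Clopper-Pearson) 95% interval of the ratio excluded 1. A library with fewer than 3 reads was set to 3 for the fold. Sequenced reads are not independent molecules, so these intervals cover counting error only and hold nothing about differences between mice. On simulated counts drawn for the 14907 genes from the mean of the libraries, the rule recovered 50 of 50 genes raised 3-fold, 48 of 50 lowered 3-fold, 50 of 50 raised 5-fold and 50 of 50 lowered 5-fold. It called 53 of 14707 unchanged genes. Both simulated libraries were drawn as Poisson counts from the same means, apart from the set folds. They hold counting error only, so the 53 calls give no error rate for differences between mice or pulldowns. The intervals held the true value for 86% of genes raised 3-fold, for 92% lowered 3-fold, for 98% raised 5-fold, for 94% lowered 5-fold and for 95.7% of unchanged genes. The simulated ratio was at first scaled by library totals and was then rescaled to the true library sizes after the coverage for genes raised 3-fold had been seen to be low.

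The 37 gene lists were fixed before the data were examined. Of these, 36 had at least 3 measured members. Each list's median log2 fold was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and a list below percentile 0.5 or above 99.5 is called outside the central 99% of random lists. By chance 0.36 of 36 lists would lie outside if the members of a list varied independently, as in the random draws. Members that vary together put more lists outside, so 0.36 gives no error rate for these lists. The size rule, the percentile limits and the 4 further alternatives named here were chosen after the file comparison and exploratory fold changes and list medians had been seen. The lists share genes, and a list's median describes these libraries only.

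The rule for named genes was fixed before the data were examined, with the size rule now standing where the adjusted p stood. It takes the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 CPM, a symbol that is not a Gm, Rik or pseudogene name, and both sleep-deprived files on the same side of both control files. It adds up to 4 called members of each list by size of change, or the 2 most abundant members where none was called, and always P2ry12 and Rpl22. Other genes are named as chosen after their values were seen. A gene that the rule takes is not reported here.

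Alternatives chosen before the data were examined were DESeq2 1.42.0 size factors, upper-quartile scaling, library size alone, TMM without mitochondrially encoded and ribosomal protein genes, no filter beyond a total of 1 read, at least 30 reads in both libraries, a transcript length offset, and leaving out each file. Alternatives added later were a 1.5-fold limit, a mean of at least 5 CPM, leaving out genes with over 50% of their exon bases inside another gene, and random lists matched on length as well, in 5 bins each. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.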

Results

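The series measured RNA recovered by a pulldown of tagged ribosomes from the hippocampus of fear-conditioned mice. How much of this RNA was bound to tagged ribosomes was not measured. Fear conditioning is a training in which a place or cue is paired with a shock. Control mice were left to sleep for 6 h after training and sleep-deprived mice were kept awake for the same 6 h. The tag was expressed under P2RY12CreER, which is active in microglia, the resident macrophages of the brain. Each group had 2 deposited files, with 14877011 and 14833320 estimated reads in control and 14473030 and 14431647 in sleep-deprived samples. The 2 files of a group differed by less than the sampling noise and were counted as 1 sample, so that every value below compares 1 library with 1 library (n = 1 per group), with no replicate check. Values are TMM-scaled CPM (counts scaled to library size), and bracketed ranges are 95% counting intervals of the ratio of sleep-deprived over control. Higher and lower, used of a called gene, mean at least 2-fold with an interval that excludes 1. A list is called outside or inside the random lists by whether its median log2 fold fell outside the central 99% of 10000 random lists matched on expression.

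**Figure D1:**
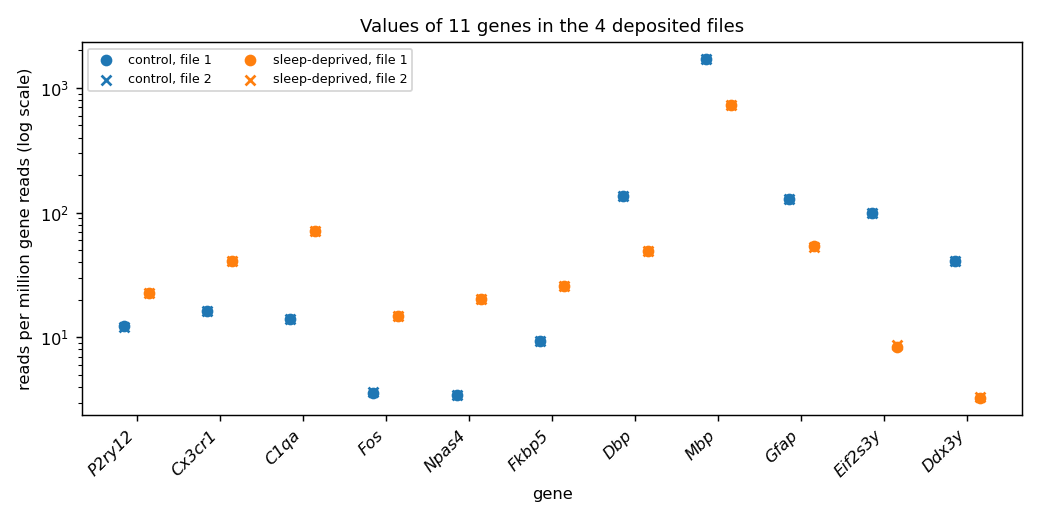
CPM on a log scale, before TMM scaling, of 11 genes in the 4 deposited files, with circles for file 1 and crosses for file 2, control in blue and sleep-deprived in orange. The markers of the 2 files of a group lie on each other for each gene shown, as for C1qa at 14.03 and 13.94 in control and 70.9 and 71.1 in sleep-deprived files.

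The comparison asked how the messages recovered by the pulldown of tagged ribosomes, aimed at microglia, differed between mice kept awake and mice allowed to sleep after learning. Microglial identity genes were higher in the sleep-deprived library, with a median of 2.57-fold over 26 genes and 16 genes called higher. Complement genes (median 1.87-fold, 6 of 13 called higher), phagocytosis receptors (1.55-fold, 6 of 22), glucocorticoid response genes (1.52-fold, 6 of 22) and immediate early genes (1.46-fold, 7 of 26, inside the random lists among genes with a mean of at least 5 CPM) were above control in the median, by less than 2-fold. Mitochondrially encoded genes (median ratio 0.456), cytosolic ribosomal protein genes (0.611), and markers of astrocytes (0.674), oligodendrocytes (0.694) and inhibitory neurons (0.660, with 0 of 10 called) were lower in the median. Of 14907 measured genes, 649 were higher and 827 lower, together 9.9%, and 88.9% lay within 2-fold. Across all measured genes the median log2 fold was 0.002, with quartiles at −0.37 and 0.36.

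Among microglial identity genes, 16 of 26 were higher and 0 lower. Fcrls, an Fc receptor-like gene typical of microglia, was at 2.35 CPM in control and 15.3 CPM in the sleep-deprived library, a ratio of 6.51 (4.51 to 9.43). Selplg, which encodes the P-selectin ligand, was at 5.36 and 33.4 CPM, a ratio of 6.24 (4.93 to 8.01). Olfml3 had a ratio of 5.41 (3.99 to 7.32), and P2ry13, a purine receptor gene, one of 5.04 (3.31 to 7.95). P2ry12, the receptor gene whose promoter drives the Cre, was at 11.97 and 23.26 CPM, a ratio of 1.94 (1.62 to 2.34) that did not reach 2-fold. Rpl22, the ribosomal protein that carries the tag, was at 90.4 and 64.4 CPM, a ratio of 0.712 (0.654 to 0.775), and at 0.479 with the transcript length offset. The summed CPM of the identity list was 809 in control and 1534 in the sleep-deprived library, a ratio of 1.89 (1.85 to 1.94). In the same libraries the general neuronal markers summed to 4347 and 3790 CPM, the astrocyte markers to 3152 and 2307 CPM, and the oligodendrocyte markers to 3808 and 2435 CPM. RNA from before the pulldown was not analysed here, so enrichment for microglia was not measured, and genes that several cell types express, such as those of the stress hormone, clock, immediate early, ribosomal and mitochondrial lists, could not be assigned to microglia.

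In the complement list, 6 of 13 measured genes were higher and 0 lower. The 3 chains of C1q, which starts the classical complement pathway, were at 13.7 and 72.5 CPM for C1qa, a ratio of 5.29 (4.56 to 6.18), at 19.0 and 79.2 CPM for C1qb, a ratio of 4.16 (3.65 to 4.75), and at 12.7 and 46.9 CPM for C1qc, a ratio of 3.70 (3.14 to 4.36). Itgb2, the shared chain of the leukocyte integrins, had a ratio of 3.11 (2.10 to 4.66). Of 22 phagocytosis and efferocytosis receptor genes, 6 were higher and 0 lower. Fcgr3, a low-affinity IgG receptor, was at 3.87 and 17.1 CPM, a ratio of 4.41 (3.28 to 5.93). Its signalling chain Fcer1g had a ratio of 2.81 (2.001 to 3.977), the adaptor Tyrobp one of 2.77 (1.96 to 4.06), and the lipid transporter Abca7, at 102 and 272 CPM, one of 2.66 (2.51 to 2.82). The identity list had a median of 2.57-fold and a 1.89-fold higher summed CPM. The medians of the complement list (1.87-fold) and of the receptor list (1.55-fold) lay below the identity median. With the identity list the complement list shares Itgam and the receptor list Mertk, Trem2 and Tyrobp.

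Markers of other neural cell types were lower or within the range of random lists. Of 15 astrocyte markers 3 were lower and 0 higher, with a median log2 fold of −0.57. These were S100b at 362 and 142 CPM, a ratio of 0.392 (0.373 to 0.413), Gfap, the astrocyte intermediate filament, at 127 and 54.5 CPM (0.430, 0.395 to 0.468), and the water channel Aqp4 at 138 and 64.1 CPM (0.466, 0.431 to 0.504). Of 14 oligodendrocyte markers 2 were lower, with a median log2 fold of −0.53. Mbp, a main protein of myelin, was at 1658 and 749 CPM, a ratio of 0.452 (0.442 to 0.462), and Opalin at 18.8 and 3.19 CPM, a ratio of 0.170 (0.121 to 0.233). The 10 inhibitory neuron markers had a median log2 fold of −0.60, outside the random lists, with 0 called and a summed CPM of 1248 in control and 1149 in the sleep-deprived library (0.920, 0.901 to 0.940), and of the most abundant ones Reln had a ratio of 1.36 (1.32 to 1.40) and Cnr1 one of 0.832 (0.792 to 0.873). General neuronal markers had a median log2 fold of −0.20 and hippocampal excitatory neuron markers one of −0.22, at percentiles 1.21 and 6.94, both inside the central 99% of random lists and with 0 called. The synaptic gene Snap25 was at 1406 and 1052 CPM (0.748, 0.733 to 0.764), Eno2 had a ratio of 1.12 (1.09 to 1.16), Ppp3ca one of 0.663 (0.642 to 0.684) and the glutamate receptor gene Gria1 one of 0.636 (0.607 to 0.666).

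The remaining cell type lists with at least 3 measured members lay inside the central 99% of random lists. Oligodendrocyte precursor markers had a median log2 fold of −0.25 over 11 genes, and 2 were lower, Cspg4 (0.419, 0.305 to 0.566) and C1ql1 (0.429, 0.178 to 0.991). Endothelial markers had a median of −0.07 over 13 genes with 0 called, and the most abundant were Slco1a4 (0.893, 0.816 to 0.978) and Flt1 (1.21, 1.08 to 1.36). Mural cell markers had a median of −0.13, with Higd1b higher (3.60, 1.67 to 9.53) and Kcnj8 (0.445, 0.237 to 0.8001) and the smooth muscle myosin Myh11 (0.490, 0.443 to 0.541) lower. Fibroblast markers had a median of −0.36 with Dcn lower (0.313, 0.205 to 0.483), and choroid plexus and ependymal markers one of −0.26 with the ependymal genes Ccdc153 (0.227, 0.118 to 0.409) and Enkur (0.407, 0.184 to 0.925) lower, the last not called with the transcript length offset. Of 7 border-associated macrophage markers 3 were higher, with a median of 0.62 at percentile 97.4. These were Cd163 at 1.95 and 4.54 CPM (2.33, 1.46 to 3.66), Lyve1 at 0.165 and 1.21 CPM (interval 2.16 to 81.3), and Folr2 at 0.231 and 1.17 CPM (5.06, 1.38 to 17.6). The ratio of Folr2 was 2.95 without control file 2, its call ended with the transcript length offset, and 63.1% of its exon bases lie in Gm10602. Of 4 monocyte and neutrophil markers, with a median of 0.22, Ly6c2 was higher on 2 control reads (interval 1.87 to 72.5). Cd79a was the 1 lymphocyte marker measured, at 0.298 and 0.780 CPM (interval 0.874 to 12.7). Erythroid markers had a median of −0.40, with Slc4a1 higher (2.74, 1.496 to 5.675) and Alas2 lower (0.448, 0.245 to 0.771).

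**Figure D2:**
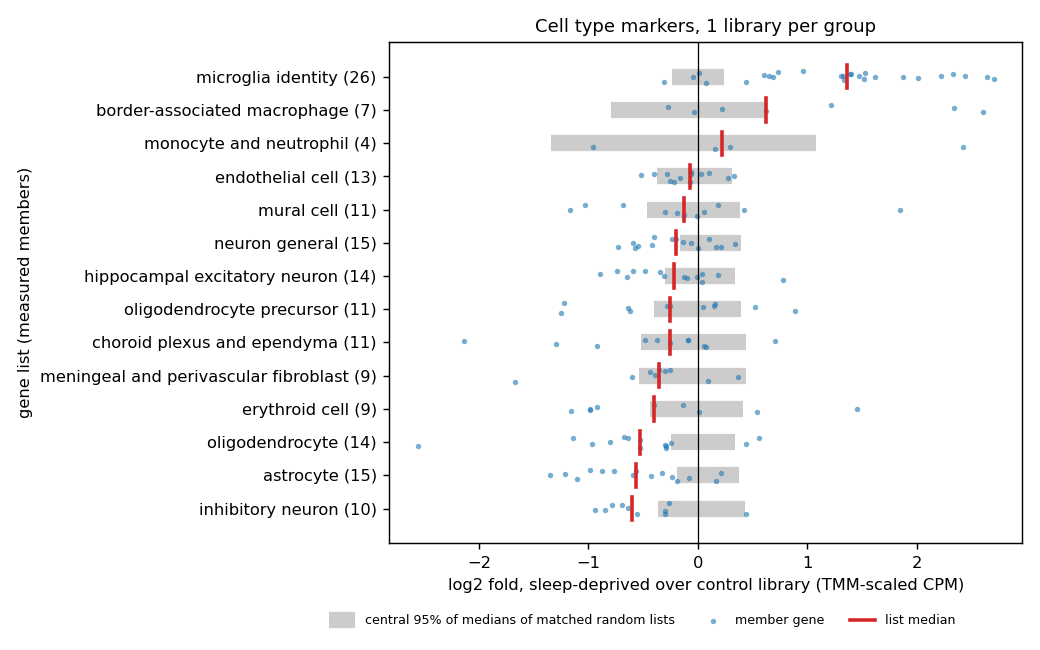
Log2 fold of the sleep-deprived over the control library (horizontal axis) for cell type marker lists (vertical axis, measured members in brackets), with member genes as blue points, list medians as red lines and the central 95% of medians of matched random lists as grey bars (lists are called outside by the central 99%). The microglia identity median lies at 1.36 against a random range of −0.24 to 0.24, and the astrocyte, oligodendrocyte and inhibitory neuron medians lie at −0.57, −0.53 and −0.60.

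Immediate early genes, transcription factors and phosphatases switched on quickly by activity or stress, had 7 of 26 measured members higher and 0 lower. Npas4, induced by neuronal activity, was at 3.37 and 20.7 CPM, a ratio of 6.13 (4.55 to 8.44). Nr4a1 was at 12.3 and 56.4 CPM (4.57, 3.90 to 5.41), Fos at 3.54 and 15.1 CPM (4.28, 3.12 to 5.81) and the phosphatase Dusp1 at 11.7 and 38.6 CPM (3.30, 2.78 to 3.93). Among genes with a mean of at least 5 CPM, an alternative added after the data were seen, the list's median log2 fold of 0.31 lay at percentile 98.9 and inside the random lists. Of 22 glucocorticoid response genes, which include targets of the stress hormone receptor, 6 were higher and 0 lower. Fkbp5, a co-chaperone of that receptor, was at 9.13 and 26.5 CPM (2.90, 2.38 to 3.55), Zbtb16 at 1.98 and 8.40 CPM (4.24, 2.81 to 6.53) and Map3k6 at 4.03 and 13.1 CPM (3.23, 2.41 to 4.40), the last at 1.99 with the transcript length offset. Dusp1 stands on both lists.

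The clock list had a median log2 fold of −0.16 at percentile 3.59, inside the random lists. Its genes lay on both sides, 9 above 0 and 12 below, and a median does not show changes in opposite directions. Of its 21 genes 2 were lower, Dbp, a transcription factor with a daily rhythm, at 132 and 50.6 CPM (0.382, 0.350 to 0.417) and Rorb at 13.6 and 6.31 CPM (0.463, 0.357 to 0.597), the last at 0.518 with the transcript length offset. The list of sleep loss genes from whole brain tissue had a median of 0.28 at percentile 98.0, with Nr4a1 higher and Dbp and Nptx2 lower, the last at 1.19 and 0.355 CPM (0.298, 0.0864 to 0.832). The unfolded protein response of the endoplasmic reticulum had a median of 0.27 at percentile 98.2, with Sdf2l1 higher at 1.12 and 4.89 CPM (4.35, 2.53 to 7.90). Cytosolic heat shock genes had a median of −0.14 with 0 of 19 called, and the chaperones Hspa8 (0.646, 0.626 to 0.666) and Hsp90ab1 (0.570, 0.549 to 0.591) were the most abundant.

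Mitochondrially encoded genes had 7 of 13 members lower and 0 higher, with a median log2 fold of −1.13. They took 3.20% of gene reads in control and 1.52% in the sleep-deprived library. The subunits of complex I mt-Nd6 (0.322, 0.315 to 0.33), mt-Nd2 (0.346, 0.340 to 0.353) and mt-Nd1 (0.377, 0.371 to 0.384) and the ATP synthase gene mt-Atp8 (0.357, 0.340 to 0.374) had the lowest ratios. Only mt-Co2, named after its value was seen, was above 1, at 1655 and 2195 CPM. Its copy Gm28661 on chromosome 1 (24614885 to 24615565), with 100% of its stretches of 31 bases in common with mt-Co2, was listed at 3720 CPM in control and 0 in the sleep-deprived library, and the pair summed to 5375 and 2195 CPM, a ratio of 0.408. Of 82 cytosolic ribosomal protein genes 24 were lower and 0 higher, with a median log2 fold of −0.71. Rpl26 was at 391 and 112 CPM (0.286, 0.270 to 0.302), Rps7 at 151 and 47.2 CPM (0.313, 0.287 to 0.341), Rps23 at 114 and 37.5 CPM (0.329, 0.297 to 0.362) and Rpl14 at 390.0 and 133 CPM (0.340, 0.323 to 0.359). Nuclear genes of oxidative phosphorylation had a median of −0.26 over 79 genes, outside the random lists, with 2 lower, Uqcc3 (0.389, 0.279 to 0.549) and Ndufb9 (0.464, 0.410 to 0.522). In the same libraries, transcripts annotated as retained introns took 10.6% of estimated reads in control and 13.2% in the sleep-deprived library, and their share was higher in 2968 of 4398 genes.

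**Figure D3:**
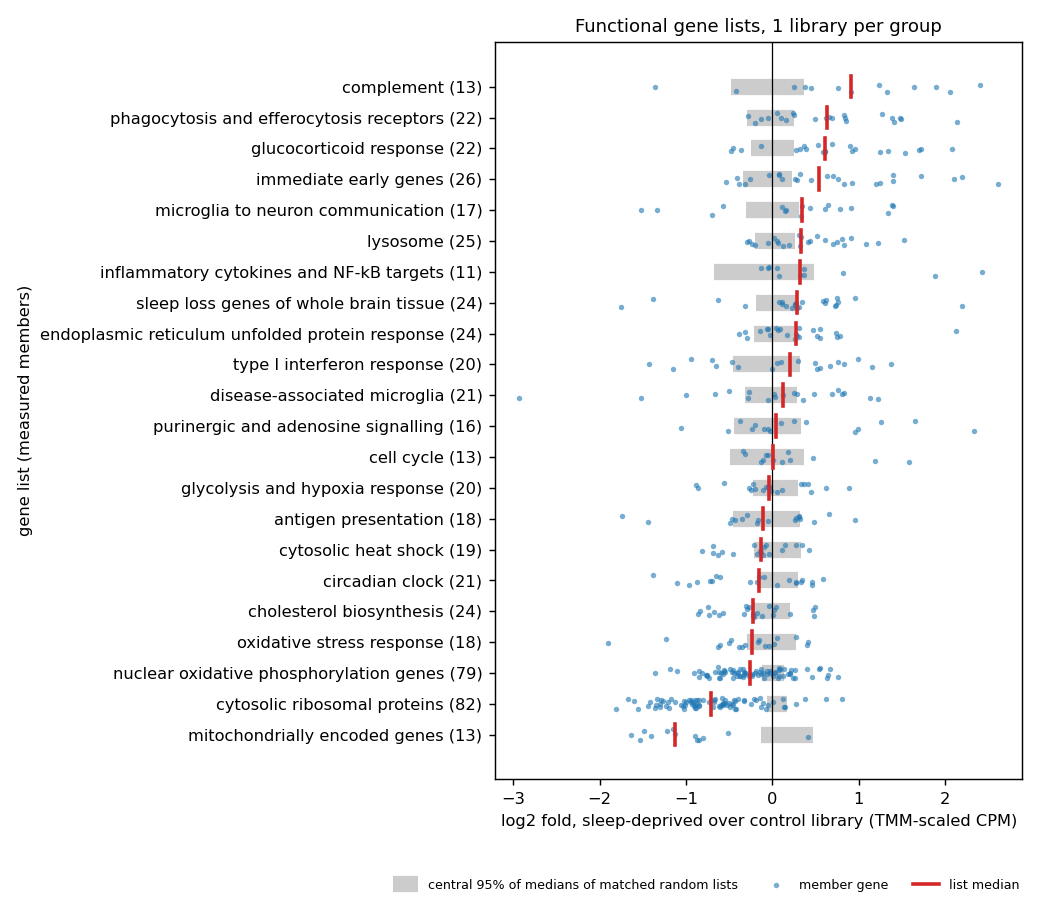
Log2 fold of the sleep-deprived over the control library (horizontal axis) for functional gene lists (vertical axis, measured members in brackets), with member genes as blue points, list medians as red lines and the central 95% of medians of matched random lists as grey bars (lists are called outside by the central 99%). Complement lies highest at a median of 0.90 and mitochondrially encoded genes lowest at −1.13.

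The disease-associated microglia, interferon response, inflammatory and antigen presentation lists lay inside the random lists. Enrichment for microglia was not measured, so these medians do not tell whether microglia were activated. Disease-associated microglia genes had a median log2 fold of 0.12 over 21 genes, with 2 higher and 3 lower. Lgals3, which encodes galectin-3, was at 5.69 and 0.745 CPM (0.131, 0.0577 to 0.241), the growth factor gene Igf1 at 4.27 and 1.49 CPM (0.349, 0.204 to 0.584), and Fabp5, named after its value was seen, had a ratio of 0.499 (0.406 to 0.616). Cd68 was at 3.84 and 8.94 CPM (2.33, 1.69 to 3.24), and at 1.29 with the transcript length offset, and lysozyme Lyz2 at 4.99 and 10.9 CPM (2.18, 1.64 to 2.90). Interferon response genes had a median of 0.20 over 20 genes, with Irf9 (2.60, 2.31 to 2.92) and Oas2 (2.21, 1.14 to 4.19) higher and Mx1 (0.371, 0.153 to 0.817) and Rtp4 (0.452, 0.235 to 0.829) lower, of which Oas2 and Rtp4 were not called with the transcript length offset. Inflammatory cytokines and NF-kB targets had 11 of 26 genes measured and a median of 0.32, with the lipopolysaccharide co-receptor Cd14 at 0.661 and 3.55 CPM (5.36, 2.69 to 11.9) and Tlr2 at 0.298 and 1.10 CPM (3.69, 1.38 to 17.6) higher. Antigen presentation genes had a median of −0.11 over 18 genes, with H2-Eb1 lower at 1.42 and 0.426 CPM (0.299, 0.0970 to 0.744).

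Lysosomal genes had a median log2 fold of 0.32 at percentile 99.4, with 3 of 25 higher. Among these were Cd68 and Ctsc, the last at 4.17 and 8.79 CPM (2.11, 1.55 to 2.91). The list lay outside the random lists with upper-quartile scaling, without control file 1 and without sleep-deprived file 1, at percentiles 99.56, 99.79 and 99.52. Microglia to neuron communication genes had a median of 0.34 at percentile 98.5, with Cx3cr1, the fractalkine receptor, at 15.9 and 41.9 CPM (2.64, 2.27 to 3.08), Trem2 (2.62, 2.06 to 3.39) and Csf1r, named after its value was seen (2.52, 2.26 to 2.81), higher, and Igf1 and the protease Mmp9 (0.395, 0.280 to 0.560) lower. Purinergic and adenosine genes had a median of 0.04 over 16 genes, with P2ry13, Adora3 (3.15, 1.40 to 8.28) and P2ry6 (2.38, 1.33 to 4.42) higher and Panx1 (0.480, 0.254 to 0.871) lower, and Adora3 and Panx1 were not called with the transcript length offset. Cell cycle genes had a median of 0.00 over 13 genes, with Ccnb2 (2.997, 2.06 to 4.44) and Tpx2 (2.27, 1.16 to 4.86) higher, the last at 0.375 with the transcript length offset. Oxidative stress genes had a median of −0.24, with Nqo1 (0.427, 0.248 to 0.675) and Osgin1 (0.268, 0.0652 to 0.831) lower. Cholesterol synthesis genes had a median of −0.23 with 0 of 24 called, Insig1 at 0.549 (0.503 to 0.599) and Lss at 0.882 (0.803 to 0.969), and Lss had a ratio of 1.34 with the transcript length offset. Glycolysis and hypoxia genes had a median of −0.04 with 0 of 20 called, Gapdh at 0.831 (0.802 to 0.860) and Pkm at 0.856 (0.824 to 0.889).

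Outside these groups, the genes that the naming rule took for their high ratios were Ikzf4, Adnp, Kcnab2, Vwf, Inpp5d and Dnd1, in falling order of ratio. Ikzf4, on 3 control reads, had a ratio with an interval of 27.4 to 396, and one of 2.74 with the transcript length offset. Adnp had a ratio of 10.2 (6.09 to 19.8), but 82.1% of its exon bases lie in Gm20716, and the ratio was 49.1 without control file 1 and 5.10 without control file 2. The potassium channel subunit gene Kcnab2 had a ratio of 5.45 (4.24 to 7.09). Vwf, which encodes von Willebrand factor and lies on chromosome 6 (125546774 to 125686679, GRCm38), was at 25.8 and 140 CPM (5.42, 4.86 to 6.06) and had a ratio of 3.14 with the transcript length offset. Its transcripts averaged 1203 bases when weighted by TPM, and whether these encode the full protein was not checked. Inpp5d, a lipid phosphatase of blood and immune cells, was at 1.98 and 10.2 CPM (5.13, 3.45 to 7.90), and Dnd1 had a ratio of 4.68 (3.20 to 6.99). C1qa, C1qb and C1qc lie side by side on chromosome 4, between 136880129 and 136898803.

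The lowest ratios among called genes with a mean of at least 5 CPM and a named symbol were those of 4 genes of the Y chromosome. The sex of the pooled mice is not given in the sources used here. If the pools differ in sex, effects of sex and of sleep loss cannot be told apart in these libraries. Uty (ENSMUSG00000068457.14, 1096861 to 1245759) was at 11.2 and 0.638 CPM, a ratio of 0.0569 (0.0255 to 0.110). Ddx3y (1260771 to 1286629) was at 40.2 and 3.37 CPM (0.0837, 0.0617 to 0.114), Eif2s3y (1010543 to 1028847) at 97.4 and 8.69 CPM (0.0892, 0.0733 to 0.107) and Kdm5d (897788 to 956786) at 41.8 and 3.79 CPM (0.0908, 0.0681 to 0.121). With the transcript length offset the ratio was 0.0372 for Uty and 0.164 for Eif2s3y. The lowest ratios after these were in Rpgrip1 at 13.01 and 1.23 CPM (0.0948, 0.0528 to 0.152), in the collagen gene Col24a1 (0.147, 0.0863 to 0.239), which stood at 0.0491 with the transcript length offset, and in Opalin. Nanos2 (0.191, 0.122 to 0.288), of which 49% of exon bases lie in Gm45058, the vesicular nucleotide transporter gene Slc17a9 (0.229, 0.146 to 0.350), the transcription factor genes Foxp2 (0.239, 0.184 to 0.308) and Spdef (0.254, 0.170 to 0.382), and Actn2 (0.260, 0.178 to 0.370) followed.

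No test between conditions was possible with 1 independent library per group, so each difference is one between these libraries and its interval leaves out variation between mice. The counts of called genes depended on the limits used, with 324 higher and 312 lower when both libraries needed at least 30 reads and 1903 higher and 1955 lower at 1.5-fold.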

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

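The tests of the agreement between files, of border macrophages and leukocytes, of neuronal RNA and of Eif2s3y alone were chosen only after the results had been seen. Reads on transcripts outside the annotation, which no comparison used, made up 0.365% of estimated reads in control and 0.340% in the sleep-deprived library. They were listed because they lie outside the measured genes, and their share was not higher in the sleep-deprived library.

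A larger share of microglial RNA in the sleep-deprived pulldown may account for the higher microglial identity genes: 39 microglia-enriched genes that stand on none of the lists, chosen before their values were seen, had a median log2 fold of 1.04, with 38 above 0 and 22 higher. Whether border macrophages or blood leukocytes also express these 39 genes was not examined, so they do not tell microglia from those cells. A smaller share of neuronal RNA alone would raise the markers of every other cell type, but astrocyte and oligodendrocyte markers, 29 genes, had a median of −0.53, with quartiles at −0.87 and −0.25, which argues against it. Border-associated macrophages or blood leukocytes cannot be excluded, since 12 of their markers had a median of 0.46 and quartiles at 0.11 and 1.63, below the 1.36 of the identity list by less than the spread of the markers, while the summed CPM of the border macrophage markers was 66.5 in control and 70.1 in the sleep-deprived library (ratio 1.05) and that of the monocyte and neutrophil markers 47.9 and 53.3 (ratio 1.11), against a ratio of 1.89 for the identity list. These sums decide little, since Maf (44.5 and 36.8 CPM) makes up most of the first and Vcan (44.6 and 49.7 CPM), also on the oligodendrocyte precursor list, most of the second. Regulation within microglia by sleep loss stays open and was not tested, because a higher microglial share and regulation would both raise these medians. A higher share alone would give genes found only in microglia a common ratio. The ratios differed, with identity list quartiles of log2 fold at 0.66 and 1.81. The intervals of P2ry12 (1.62 to 2.34) and Fcrls (4.51 to 9.43) do not overlap. Which genes only microglia express in these libraries was not measured, so the spread does not settle the question.

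The Y-linked genes Uty, Ddx3y, Eif2s3y and Kdm5d were at 5.69%, 8.37%, 8.92% and 9.08% of their control level, and Gm21748, the only other measured gene of the Y chromosome, was at 10.8%. Pools of different sex makeup are a candidate explanation, since the sex of the mice is not given in the sources used here: of 4 X-linked genes that escape inactivation in females, chosen before their values were seen, Kdm5c (ratio 2.08), Kdm6a (1.70) and Ddx3x (1.15) were above 1, with a median log2 fold of 0.49 at percentile 95.4, but the stated prediction that all 4 would be higher was missed, with Eif2s3x at 0.677, so it stays undecided. Reads moved by the estimation from Y copies to their X copies were the other explanation: Eif2s3x did not gain what Eif2s3y lost (gain over loss −0.357), which argues against it for that pair. Summed over the 4 pairs the gain over loss was 0.780, inside the range of 0.7 to 1.3 stated before the result. It was judged undecided after the single pairs were seen, each of which lay outside that range. They were −0.357 for Eif2s3y, 1.37 for Ddx3y, 1.44 for Kdm5d and 5.87 for Uty. A gain above the loss is more than moved reads alone can give. If the pools differ in sex, sex and sleep loss cannot be told apart in any gene of these libraries, because each group is 1 library.

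The 2 files of each group agreed more closely than sampling noise allows. Independent sequencing of one library gives a chi-square per degree of freedom of about 1, and the larger of the values was 0.335, which argues against it. Reads of the same fragments in both files, such as the ends of read pairs quantified apart, may account for this: the ratio of file 1 to file 2 per gene correlated between the groups, across 304 genes with at least 5000 reads in each file, at r = 0.580, and at 0.317 with at least 1000 reads and 0.0750 with at least 200. These correlations are across genes, which are not independent replicates, and no biological explanation was tested.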

How the results depend on the processing

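The 1.5-fold limit, the mean of at least 5 CPM, the exon-sharing filter and the length-matched random lists were chosen after seeing the data. No paired analysis was possible because each group holds 1 independent library, and the planned tests (edgeR with and without robust, DESeq2 Wald, limma voom, replicate block, camera, fry, adjusted p thresholds) were not run for the same reason. The main counts were 649 higher and 827 lower. With at least 30 reads in both libraries they were 324 and 312, and with a mean of at least 5 CPM 286 and 283, since fewer genes enter. At 1.5-fold they were 1903 and 1955, since the limit is lower. The other scalings, no filter, the length offset and the exon-sharing filter gave 572 to 825 higher and 788 to 1000 lower. The length offset kept 558 of the 649 and 744 of the 827. Leaving out a file gave 641 to 670 higher, 821 to 844 lower and 11 to 12 lists outside the random lists, but this leaves out no independent library. The number of lists outside was 11, and 10 to 12 under all alternatives run. Lysosome joined under upper-quartile scaling and without control file 1 or sleep-deprived file 1, and immediate early genes dropped out with a mean of at least 5 CPM; the cause was not tested. The ratio of summed CPM of the microglia identity list was 1.89 and with library size alone 1.82, since that leaves out the TMM factor. Tpx2 reversed with the transcript length offset, from a log2 fold of 1.18 to −1.42; the cause was not tested. Depth limits the low genes, and many of the called genes had fewer than 30 reads in a library.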

Other observations

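All families and features in this part were chosen after the data had been seen. In 11 families drawn from gene symbols, 3 had medians outside the central 99% of matched random lists, all lower in the sleep-deprived library, and 2 of these are overlapping versions of the potassium channel family. Spectrins, which form the membrane skeleton, had a median log2 fold of −0.83 over 5 genes, with 0 called. Sptan1, among the most abundant genes in both libraries, was at 13175 and 7434 CPM, a ratio of 0.564 (0.560 to 0.568). Voltage-gated potassium channels had a median of −0.49 over 14 genes of Kcna to Kcnd, and one of −0.58 over the 11 genes without Kcnd, with 2 lower. The other families lay inside the random lists. CDC-like kinases, which phosphorylate splicing factors, had a median of 0.59 with 4 of 4 above 0 and 0 called. SR splicing factors had a median of 0.43 with 2 of 11 higher, among them Srsf5 at 1011 and 2839 CPM, a ratio of 2.81 (2.76 to 2.86), and hnRNP proteins one of 0.26. Clustered protocadherins, adhesion proteins of neurons, had a median of −0.27 with 12 of 55 lower and 1 higher. Collagens had a median of −0.18, V-ATPase subunits one of −0.15, proteasome subunits one of −0.13 and translation initiation factors one of −0.12.

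Among 4398 genes with at least 200 reads in each library and 20 retained-intron reads, 2968 had a higher share of retained-intron transcripts in the sleep-deprived library and 1428 a lower one, with a median difference within genes of 1.51 percentage points and medians over genes of 9.92% and 13.2%. Transcripts annotated for nonsense-mediated decay took 4.03% and 4.59%. Protein-coding transcripts took 79.7% and 77.6%.

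Copies of mitochondrial genes on chromosome 1 have sequence in common with the mitochondrial genes themselves. How the estimation divided reads between them was not traced. Gm28437 (24613189 to 24613971), with 100% of its stretches of 31 bases in mt-Co3, was listed at 1414 and 14.9 CPM, and the pair summed to a ratio of 0.399 where mt-Co3 alone had 0.555. Gm29216 (24615706 to 24616197), with 97.2% in mt-Co1, was listed at 5424 and 1782 CPM, and that pair summed to a ratio of 0.401 where mt-Co1 alone had 0.456. Together with the sum of mt-Co2 and Gm28661, at 0.408, the 3 summed ratios lay closer to each other than those of the mitochondrial genes alone, where mt-Co2 had 1.33. Mitochondrial genes and unprocessed pseudogenes together took 4.32% of gene reads in control and 1.74% in the sleep-deprived library.

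The log2 fold showed no trend with transcript length across 14907 genes (Spearman's rho 0.001), and genes are not independent replicates.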
